A study of Mus musculus with 6 samples.

How the data were processed

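RNA was measured by bulk sequencing of tumours grown from B16, a mouse melanoma cell line, in 6 libraries. Per the labels, 3 tumours came from mice given an immune checkpoint inhibitor (ICI, replicates 1, 2 and 3) and 3 from mice given radiation together with the inhibitor (RT_ICI, replicates 1, 2 and 4). The target of the inhibitor, the radiation dose, the time of harvest and whether the harvested tumour lay inside the radiation field are not given in the sources used here. Each library was treated as 1 replicate. The labels do not say outright that each came from a different animal, so p-values measure the spread between these libraries.

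The authors deposited whole-number counts per gene, 1 row for each of 34665 Ensembl genes. Per the submitters' processing notes, HISAT2 was the aligner named and GRCm38 and mm10 were the genome builds. The counting tool, the annotation release, the strand setting and all versions are not given in the sources used here. Some near-identical gene copies held almost equal counts in the deposited table. The nuclear pseudogene Gm28661 carried 98.3% to 99.4% of the count of mt-Co2 in every library, and Gm28437 98.2% to 99.4% of that of mt-Co3. Reads that fit both places of these pairs appear to have been counted at each. Other pairs were less alike. Oas1g averaged at most 38.7 CPM in either group, against 77.5 for the near-identical Oas1a in ICI. Where reads were counted at several places, they enter the library totals more than once. The 11 nuclear copies of mitochondrial genes held 2.19% of counts in ICI and 5.94% in RT_ICI on average. A total of 83 rows had no gene symbol and kept their Ensembl identifier.

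The library totals ranged from 22543721 to 45624013 counts. At this depth the 95% Wilson interval of the shares of counts printed here reaches at most 0.0131 percentage points to either side. These intervals, and a floor of 3 counts per library used for genes at 0, cover counting error only. No 2 libraries agreed within sampling noise: the chi-square statistic per degree of freedom was at least 40.0 for every pair.

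Differential expression was computed from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 16924, libraries were scaled by TMM, dispersions were estimated robustly, and the 2 groups were compared with the robust quasi-likelihood test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold change. Adjusted p-values in the text come from this test unless another is named. Levels are TMM-normalized CPM, the count scaled to library size. Standard errors (SE) of a log2 fold change were taken from the fitted coefficient and the F statistic.

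Before the data were examined, 34 gene lists with 620 entries (616 different genes) were fixed for tumour, stromal, immune, stress and metabolic programmes and for other cell types that a tumour piece can hold. Lists with at least 5 tested members, 32 in number, were tested with camera at a preset correlation of 0.01 between genes and adjusted over the lists. An estimated correlation and the directional test of fry were computed beside it. Camera asks whether a list moved further than the other genes, and fry asks whether its genes moved one way on balance. The named genes followed a rule fixed at the same time. It took the 8 largest rises and falls among called, properly named genes with a mean of at least 1 CPM in the higher group and no overlap between the groups. It added a fixed set of stromal, immune and tumour genes, up to 4 members of each called list and up to 2 members of each list for another cell type. Other genes that are named were chosen after their values were seen. Not every gene that the rule took is reported here. The hypoxia and glycolysis list counts 21 rows for 20 symbols because 1 symbol has 2 rows.

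Positions, exon overlaps (bedtools 2.31.1), near-identical stretches of at least 200 bases at 95% identity (blastn 2.17.0), transcript lengths and GC contents came from GENCODE release M21 on GRCm38. Of the deposited identifiers, 33858 were found there, and 99.6% of the tested genes had a length and a GC content, taken from the longest transcript. Of the 87 named genes, 8 shared at least 20% of their length with another gene by exon overlap or near-identity. They were Atp2a1, Cox5b, Fen1, Gbp6, Ifng, Oas1a, mt-Nd4 and mt-Nd5, and their values are uncertain to that extent.

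Other settings tried were median-of-ratios and upper-quartile scaling, no filter on low counts, a stricter filter of 1 CPM in 3 libraries, DESeq2 1.42.0 on the genes, limma-voom (limma 3.58.1), robust estimation turned off, the replicate number as a block, and leaving out each library in turn. Others were an adjusted p under 0.1, a log2 fold change of at least 1 in addition, and leaving out mitochondrially encoded genes before scaling. For the comparison of whole libraries they were a prior count of 0.5 in place of 2 and the 500 most variable genes. Corrections chosen after seeing the data were a smooth per-library correction for transcript length and GC content, the same correction without RT_ICI replicate 1, and leaving out mitochondrial genes with their copies, ribosomal RNA rows and unnamed rows.

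The pipeline was tested on simulated data built from the means, dispersions and library sizes of these 6 libraries, with 200 genes changed between the groups. The changed genes were drawn only from those above a minimum mean CPM, so recovery at low levels was not measured. Over 16673 simulated genes, 96.0% of 4-fold changes and 55.0% of 2-fold changes were called. There 12 unchanged genes were called, 7.36% of all calls. In a run on 16686 genes, both of 2 lists changed 2-fold were called in their direction and 0 other lists were. Each simulated gene varied on its own, so genes of a list were not correlated. In the data the estimated correlation reached 0.922, for skeletal muscle. The run therefore leaves open how often lists are called falsely at the preset correlation of 0.01. With a simulated trend on length and GC content, 734 unchanged genes were called without the correction (16683 genes) and 9 with it (16618 genes).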

Results

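The series compared groups of B16 tumours. The ICI tumours came from mice given an immune checkpoint inhibitor alone (n = 3). The RT_ICI tumours came from mice given radiation and the inhibitor (n = 3). Whether they lay inside the radiation field is not given. The title of the series places the work in the study of fibroblasts that express Sfrp2, of the niche around vessels and of responses outside that field. The question addressed is which transcripts differed when radiation was added to checkpoint inhibition. The ICI libraries held 32201558, 37980103 and 43109047 counts (replicates 1, 2 and 3) and the RT_ICI libraries 32855257, 45624013 and 22543721 (replicates 1, 2 and 4).

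Libraries of the groups lay apart on the first principal component, which held 41.8% of the variance of log2 CPM. The second component held 28.0% and separated RT_ICI replicate 1 from RT_ICI replicate 4. Pearson correlations across genes averaged 0.974 within ICI, 0.961 within RT_ICI and 0.950 between the groups. With only the 500 most variable genes the first component no longer separated the groups. RT_ICI replicate 1 stood apart in several measures. It had counts on 29748 rows, against 22763 to 24891 in the other 5 libraries, and ribosomal RNA rows took 1.35% of its counts (95% Wilson interval 1.35% to 1.35%) against at most 0.295% elsewhere. A row with no symbol, ENSMUSG00000075014, chosen after its values were seen, held 15516 counts there and between 1 and 2634 in the others.

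**Figure D1:**
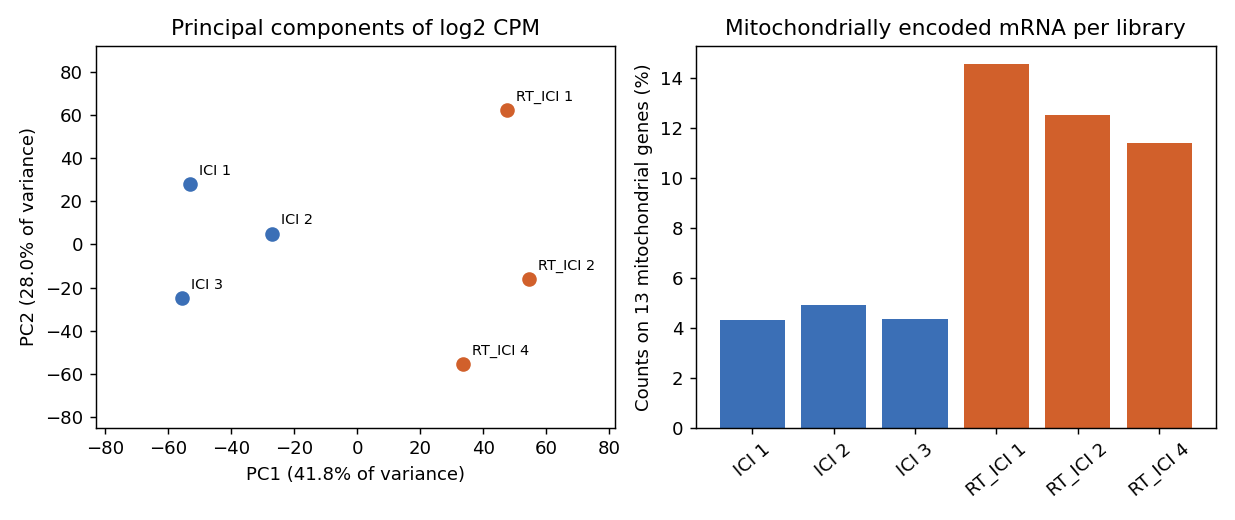
Left, the 6 libraries on the first and second principal components of log2 CPM. Right, the share of counts on the 13 mitochondrially encoded protein genes in each library, in percent. The ICI libraries sit between 4.33% and 4.91% and the RT_ICI libraries between 11.4% and 14.6%.

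All 13 mitochondrially encoded genes were higher in RT_ICI tumours, by a median log2 fold change of 1.76. Klf2 rose 3.64-fold, Fosb 7.32-fold, and Atm was 3.08-fold lower. As lists, by camera at a preset correlation, mitochondrially encoded, immediate early and adipocyte genes were higher than with the inhibitor alone, and cell cycle, DNA repair and interferon response genes were lower. With an estimated correlation adjusted p = 0.307 for the mitochondrial list, 0.775 for the immediate early and adipocyte lists and 0.930 for the others, and 0 of 32 lists were called (2 higher and 0 lower at an unadjusted p under 0.05), while fry called 1 higher (the mitochondrial list) and 0 lower. Fry gave adjusted p from 0.0759 to 0.584 for the other 12 lists that camera called. With the 6 libraries split otherwise, camera at the preset correlation called up to 19 lists in 1 direction. The real groups gave 7 higher and 6 lower. Of 16924 tested genes, 754 were higher and 799 lower in RT_ICI, and 431 of the former and 156 of the latter differed by at least 2-fold. All 1553 called genes had no overlap between the 3 and 3 libraries. Over all tested genes 37.2% had none, where chance gives 10%. The counts depended on single libraries. Both were 0 without ICI replicate 1 or without RT_ICI replicate 2, with 3701 and 4107 genes at an unadjusted p under 0.05 in edgeR. They were 2 and 0 without ICI replicate 3, 234 and 291 without ICI replicate 2, 81 and 16 without RT_ICI replicate 4, and 1564 and 1545 without RT_ICI replicate 1. In each of these 6 fits every called gene that was tested kept its sign and an unadjusted p under 0.05. Those genes were picked in the same libraries with no overlap between the groups. Keeping the sign was therefore all but fixed, and this is no separate support for the calls. Upper-quartile scaling gave 1046 higher and 497 lower, so the share of calls that were higher went from 48.6% to 67.8%.

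The calls followed transcript length and GC content. The median log2 fold change went from 0.37 in the shortest decile of transcripts to -0.26 in the longest, and from -0.14 in the lowest decile of GC content to 0.29 in the highest. In the shortest decile 126 genes were higher and 15 lower, and in the longest 31 were higher and 231 lower. A per-library correction for both properties, chosen after seeing the data, left 261 genes higher and 229 lower, of which 452 had been called in the same direction before it. Among the 1096 calls that it ended, the median absolute log2 fold change went from 0.78 to 0.58 with a median SE of 0.17 before and 0.16 after, and 1030 stayed at an unadjusted p under 0.05. Without RT_ICI replicate 1 the same correction gave 1272 higher and 1355 lower.

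**Figure D2:**
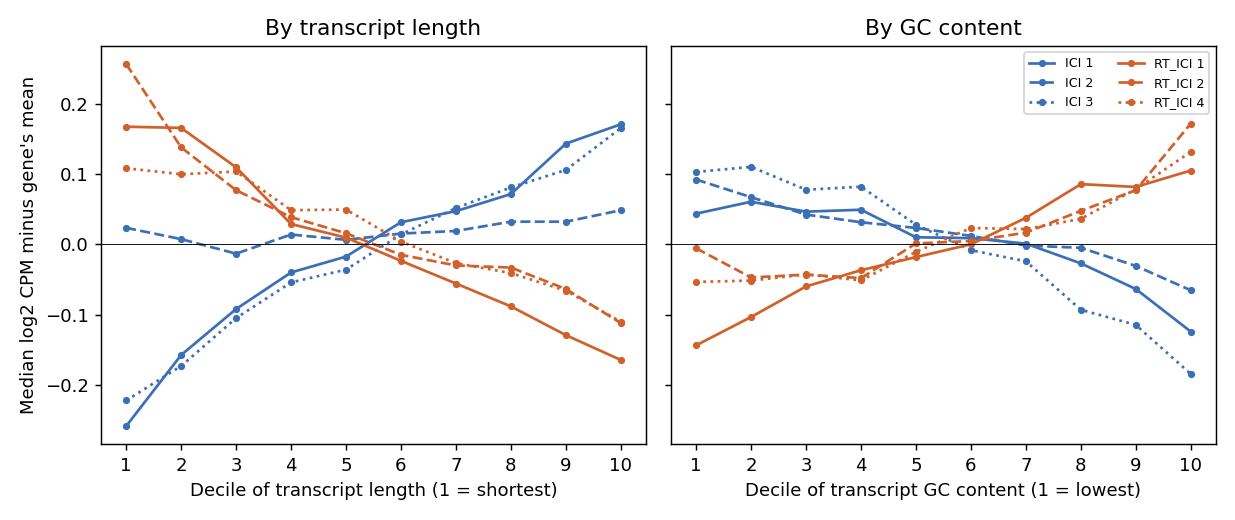
Median of each gene's log2 CPM minus its mean over the 6 libraries, by decile of transcript length (left) and of GC content (right), 1 line per library. RT_ICI libraries run from above 0 in the shortest decile to below 0 in the longest, and ICI replicate 2 is nearly flat for length.

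The largest rises included immune, metabolic and imprinted genes. Cxcl13, the chemokine that attracts B cells (chromosome 5, 95956951 to 95961068 on GRCm38), had 0 counts in all ICI libraries and 3.66 ± 2.79 CPM (SD, n = 3) in RT_ICI, at least 48.9-fold higher against a floor of 3 counts per library (adjusted p = 0.0267, edgeR). RT_ICI replicate 1 held 6.67 CPM of Cxcl13 against 1.17 and 3.13 in RT_ICI replicates 2 and 4, and without it the bound was 28.7-fold. Peg3, a paternally expressed imprinted zinc finger gene (chromosome 7, 6703892 to 6730431), rose 14.2-fold from 1.44 ± 0.831 to 20.3 ± 13.5 CPM. The neighbouring imprinted gene Zim1 (chromosome 7, 6671269 to 6696450) rose 14.5-fold to 1.37 ± 1.20 CPM. Marco, a scavenger receptor of macrophages, rose 17.8-fold to 7.93 ± 6.11 CPM. Ucp3, a mitochondrial uncoupling protein of muscle and fat, rose 37.3-fold to 2.91 ± 3.20 CPM, and was highest in RT_ICI replicate 1 at 6.53 CPM. Slc10a6, a steroid sulfate transporter, rose 19.8-fold, Rasd1, a small GTPase induced by dexamethasone, 16.5-fold, and the aminopeptidase gene Lvrn 15.2-fold. Adjusted p-values of these genes lay between 0.0252 and 0.0421. Without RT_ICI replicate 1 the log2 fold changes of Slc10a6 (4.31), Marco (4.16), Peg3 (3.83), Ucp3 (5.22) and Zim1 (3.86) were 3.03, 3.49, 3.21, 3.86 and 2.91, and without ICI replicate 2 those of Ucp3 and Zim1 were 6.16 and 5.08. After the correction for length and GC content, Ucp3 and Zim1 were at adjusted p = 0.0530 and 0.0539 and the other 6 stayed under 0.05.

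The largest falls included genes of myeloid cells and of antiviral defence. Cx3cr1, the fractalkine receptor of monocytes and tissue macrophages (chromosome 9, 119901616 to 120069879), was 9.32-fold lower in RT_ICI, at 0.189 ± 0.0836 CPM against 1.86 ± 1.41 (SD, n = 3). Fcrls, an Fc receptor-like gene of macrophages, was 8.50-fold lower, and Cd180, a toll-like receptor relative of B cells and macrophages, 3.99-fold lower. Apln, which encodes the vascular peptide apelin (chromosome X, 48025146 to 48034853), fell from 36.4 ± 20.2 to 5.41 ± 1.55 CPM, 6.75-fold. Ch25h, the interferon-induced cholesterol 25-hydroxylase, was 6.15-fold lower, Oas1h 8.08-fold lower and the MHC class Ib gene H2-T24 4.83-fold lower. Fen1, a flap endonuclease of DNA replication, was 4.47-fold lower at 0.955 ± 0.518 CPM. The antisense gene Gm10143 covers 78.8% of the Fen1 exons, and without strand information reads of the pair cannot be told apart. Adjusted p-values of these 8 genes lay between 0.0266 and 0.0461. Without ICI replicate 1 the log2 fold changes of Cx3cr1 (-3.22) and Oas1h (-3.02) were -2.48 and -2.09, and without RT_ICI replicate 1 that of Ch25h (-2.62) was -3.44. After the length and GC correction Cx3cr1, Oas1h and H2-T24 were at adjusted p = 0.0530, 0.0590 and 0.0515, and the other 5 stayed under 0.05.

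All 13 mitochondrially encoded protein genes rose in RT_ICI, as a list (camera adjusted p = 3.99e-39) and singly, with a median log2 fold change of 1.76. With an estimated correlation the list had adjusted p = 0.307, and with fry 0.0297. Over the list alone all 13 were also called. These genes encode subunits of the respiratory chain. They took 4.53% ± 0.331 of counts in ICI and 12.8% ± 1.61 in RT_ICI (SD, n = 3 each, 2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). mt-Nd5, of complex I, rose from 1789 ± 308 to 7077 ± 770 CPM, 3.96-fold (log2 fold change 1.98, SE 0.19). mt-Cytb, of complex III, rose 3.58-fold, mt-Nd4 3.63-fold and mt-Nd1 3.39-fold. Of 21 nuclear-encoded genes of oxidative phosphorylation, 3 rose, 0 fell and 18 did not pass, with 4 past the threshold when adjusted over the list alone. Ndufa1 rose 1.77-fold, Cox6c 1.61-fold and Ndufa8 1.44-fold. As a list they were called higher (camera adjusted p = 0.0291, and adjusted p = 0.930 with an estimated correlation). The list lay 0.34 above each gene's mean log2 CPM in RT_ICI replicate 1 and at 0.03 and -0.04 in RT_ICI replicates 2 and 4. In ICI it lay at -0.17, -0.03 and -0.14. That call ended without ICI replicate 1 (adjusted p = 0.0810), without RT_ICI replicate 1 (0.448) and after the length and GC correction (0.259). With that correction and without RT_ICI replicate 1 the direction of the list reversed. After that correction Ndufa1, Cox6c and Ndufa8 were at adjusted p = 0.0553, 0.0532 and 0.274.

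**Figure D3:**
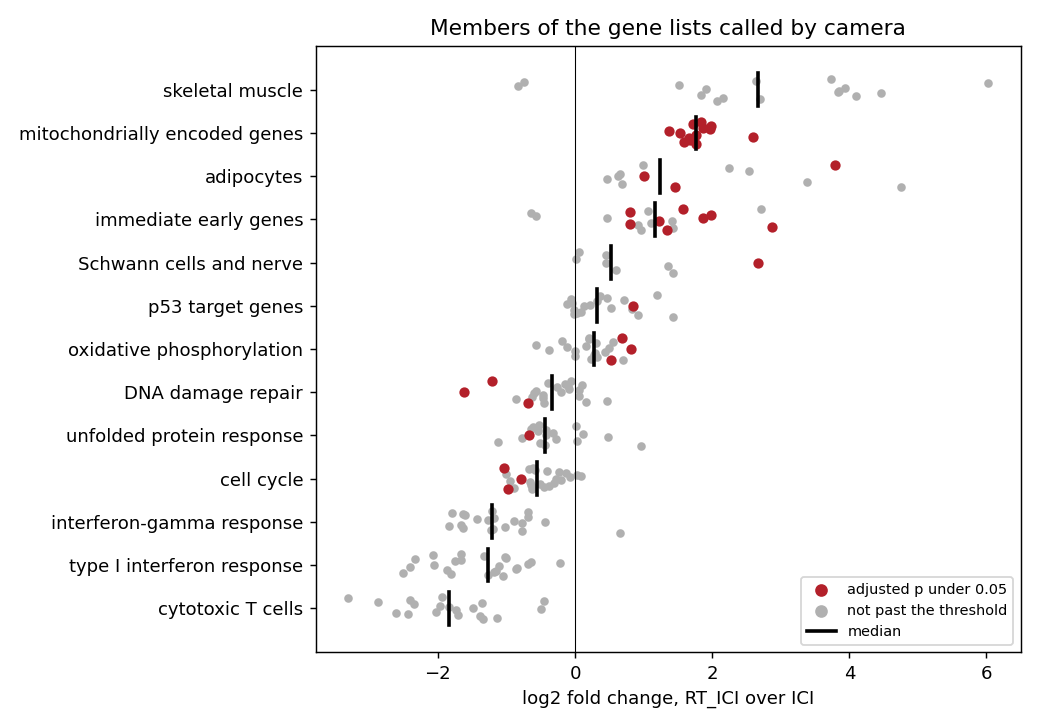
Log2 fold change of RT_ICI over ICI for each tested member of the 13 lists called by camera, 1 point per gene, with the list's median as a black bar. All 13 mitochondrially encoded genes are past the threshold, and 0 members of the interferon and cytotoxic T cell lists are.

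Immediate early genes, transcription factors and feedback regulators that respond within minutes to growth factors and stress, rose as a list (camera adjusted p = 4.15e-09, and adjusted p = 0.775 with an estimated correlation). RT_ICI replicate 1 stood apart, with the list 1.31 above each gene's mean log2 CPM, against 0.01 and 0.24 in RT_ICI replicates 2 and 4 and -0.65, -0.43 and -0.48 in ICI. Of 18 members 8 rose, 0 fell and 10 did not pass, with 14 higher when adjusted over the list alone. Klf2, a transcription factor of quiescent endothelium and T cells (chromosome 8, 72319033 to 72321656), rose 3.64-fold from 5.30 ± 0.794 to 19.3 ± 2.01 CPM (log2 fold change 1.86, SE 0.19). Fosb rose 7.32-fold to 30.5 ± 18.2 CPM, Zfp36, which promotes decay of cytokine mRNA, 2.54-fold, and Nr4a1 1.75-fold. RT_ICI replicate 1 had the highest value of the 3 RT_ICI libraries for each of these 4 genes, and without it the log2 fold change of Fosb was 2.28 against 2.87. After the length and GC correction Klf2, Zfp36 and Fosb stayed called and Nr4a1 did not (adjusted p = 0.0767).

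Genes of fat cells were higher in RT_ICI as a list (camera adjusted p = 0.000159, and adjusted p = 0.775 with an estimated correlation). ICI replicate 3 stood nearer to RT_ICI than to its own group. The adipocytes list lay 0.54 above each gene's mean log2 CPM there, against -2.20 and -2.22 in ICI replicates 1 and 2 and 0.99 to 1.61 in RT_ICI. Of 12 tested members 3 rose, 0 fell and 9 did not pass, and the same numbers were called when adjusted over the list alone. Plin4, a lipid droplet coat protein, rose 13.8-fold from 1.77 ± 1.97 to 24.9 ± 7.65 CPM, a log2 fold change of 3.79 that was 5.28 without ICI replicate 3. Of members chosen after their values were seen, Cfd, Pck1 and Cidec averaged 30.5, 4.98 and 5.33 CPM against 5.18, 0.167 and 0.488, and Adipoq and Plin1 1.56 and 0.708 against 0.759 and 0.439. They were not called (adjusted p = 0.401, 0.156, 0.191, 0.629 and 0.804). The mean log2 CPM of Adipoq, Plin1 and Cfd was 1.86 in ICI replicate 3, -3.49 and -3.99 in ICI replicates 1 and 2, and 1.49 to 1.98 in RT_ICI. Fabp4, a fatty acid binding protein of fat cells, macrophages and endothelium, rose 2.76-fold to 133 ± 46.7 CPM, and Lipe, hormone-sensitive lipase, 2.01-fold. Retn was at 1.19 ± 0.237 against 0.237 ± 0.339 CPM and did not pass (adjusted p = 0.137), with a log2 fold change of 2.25 that was 4.74 without ICI replicate 3. Genes of Schwann cells and nerve were also higher as a list (camera adjusted p = 0.0242, and adjusted p = 0.775 with an estimated correlation), with 1 of 8 members called over all genes and 4 when adjusted over the list alone. Scn7a, a sodium channel gene, was at 1.75 ± 0.755 against 0.650 ± 0.193 CPM (adjusted p = 0.0726). The nerve list was not called without ICI replicate 2 (adjusted p = 0.0613) or without RT_ICI replicate 1 (0.0599). After the length and GC correction Plin4 and Lipe were at adjusted p = 0.0587 and 0.0733, and Fabp4 stayed called.

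Skeletal muscle genes varied by library more than by group. The 18 muscle genes took 0.277% and 0.152% of counts in RT_ICI replicates 1 and 2 but 0.00304% in RT_ICI replicate 4, and 0.0330%, 0.0267% and 0.000703% in ICI replicates 1, 2 and 3. The list was called higher (camera adjusted p = 0.0311, and adjusted p = 0.930 with an estimated correlation) although 0 of 16 tested members passed, over all genes or adjusted over the list alone. Myh4, a fast myosin heavy chain, was at 331 ± 347 against 5.08 ± 7.19 CPM (adjusted p = 0.183) and Myoz1 at 13.8 ± 12.8 against 0.908 ± 0.851. Over the fits that leave out 1 library the log2 fold change of Myh4 (6.03) ran from 4.90 without RT_ICI replicate 1 to 8.48 without ICI replicate 2, and that of Myoz1 (3.93) from 3.10 to 4.99 in the same fits. At an unadjusted p under 0.05 in edgeR 0 passed, and limma-voom called 0 and DESeq2 2. The list was not called without RT_ICI replicate 1 (adjusted p = 0.411), RT_ICI replicate 2 (0.163) or ICI replicate 3 (0.352). Of 4 tested keratinocyte genes, too few for the list test, 0 were called over all genes and 3 were higher when adjusted over the list alone. Perp and Sbsn were at 0.983 ± 0.349 and 3.74 ± 0.463 CPM in RT_ICI, against 0.216 ± 0.168 and 2.26 ± 0.396, and the log2 fold change of Perp (2.18) was 2.87 without ICI replicate 2. In edgeR 3 keratinocyte genes were higher at an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. Of 7 genes of red cells and mast cells 0 were called, over all genes or adjusted over the list alone (camera adjusted p = 0.0958), with 1 lower at an unadjusted p under 0.05 in edgeR, 2 by DESeq2 and 0 by limma-voom. The red cells and mast cells list was called lower without ICI replicate 1 (adjusted p = 0.00183), ICI replicate 2 (0.0389) or RT_ICI replicate 2 (0.0382). Hbb-bs was at 606 ± 842 CPM in ICI and 60.5 ± 42.4 in RT_ICI, with 1576 CPM in ICI replicate 3, and Slc4a1 at 1.66 ± 1.77 and 0.214 ± 0.168. Their log2 fold changes (-3.32 and -2.85) were -0.999 and -1.48 without ICI replicate 3 and -4.02 and -3.76 without RT_ICI replicate 2.

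Cell cycle and DNA repair genes were lower in RT_ICI as lists, and ICI replicate 3 stood highest. The cell cycle list lay 0.70 above each gene's mean log2 CPM there, against 0.04 and -0.01 in ICI replicates 1 and 2 and -0.12 to -0.40 in RT_ICI. The DNA repair list lay at 0.38 there, at 0.14 and 0.01 in the other ICI libraries and at -0.12 to -0.24 in RT_ICI. Of 24 cell cycle genes 3 fell, 0 rose and 21 did not pass, with 8 lower when adjusted over the list alone (camera adjusted p = 1.5e-05, and adjusted p = 0.930 with an estimated correlation and 0.424 with fry). Mcm4 and Mcm2, subunits of the replicative helicase, were 2.06-fold and 1.96-fold lower, Mcm2 at 135 ± 17.7 against 264 ± 63.4 CPM. Top2a, the topoisomerase of dividing cells, was 1.72-fold lower, and Ccna2 was at 44.7 ± 4.06 against 86.5 ± 32.3 CPM (adjusted p = 0.0506, and 0.0493 without ICI replicate 2). Mki67, the proliferation marker, was at 204 ± 64.2 against 215 ± 73.3 CPM and was not called (adjusted p = 0.888). Of 22 DNA repair genes 3 fell, 0 rose and 19 did not pass, with 6 lower when adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.930 with an estimated correlation). Atm, the kinase that senses double-strand breaks (chromosome 9, 53439149 to 53536740), was 3.08-fold lower at 8.18 ± 1.21 against 25.2 ± 2.91 CPM (log2 fold change -1.62, SE 0.18). Brca1 was 2.31-fold lower and Lig4, the ligase of end joining, 1.61-fold lower, while Parp1 was at 96.3 ± 8.19 against 132 ± 14.5 CPM (adjusted p = 0.0691). With the length and GC correction Atm, Brca1, Mcm2 and Mcm4 stayed called, and Lig4 (adjusted p = 0.0930) and Top2a (0.114) did not.

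The p53 target genes were higher as a list (camera adjusted p = 0.0409, and adjusted p = 0.775 with an estimated correlation), with 1 of 19 members called over all genes and adjusted over the list alone. Phlda3, a p53-induced inhibitor of Akt, rose 1.79-fold from 106 ± 18.9 to 190 ± 20.4 CPM, and was at adjusted p = 0.105 after the length and GC correction. Bax, Eda2r and Btg2 were at 135 ± 37.0, 4.35 ± 0.994 and 18.3 ± 14.7 CPM in RT_ICI, against 75.9 ± 12.4, 2.29 ± 0.501 and 6.79 ± 0.974, and did not pass. RT_ICI replicate 1 held 35.2 CPM of Btg2 against 11.4 and 8.35 in RT_ICI replicates 2 and 4. In the fit that left it out, the log2 fold change of Btg2 was 0.55 against 1.43, and Bax and Eda2r passed (adjusted p = 0.0139 and 0.0431). After the length and GC correction with all libraries, the log2 fold change of Bax was 0.38 against 0.83 (adjusted p = 0.288). Those of Eda2r and Btg2 were then 1.13 against 0.92 and 1.42 against 1.43 (adjusted p = 0.0697 and 0.141). Cdkn1a, the p21 cell cycle inhibitor, was at 269 ± 69.9 against 194 ± 33.6 CPM (adjusted p = 0.175). The list was not called without ICI replicate 3 (0.104) or without RT_ICI replicate 1 (0.0528). Genes of the unfolded protein response were lower as a list (camera adjusted p = 0.0409, and adjusted p = 0.930 with an estimated correlation). ICI replicate 2 stood apart, 0.71 above each gene's mean log2 CPM, against -0.15 and -0.14 in ICI replicates 1 and 3. RT_ICI replicates 1, 2 and 4 lay at -0.39, -0.33 and 0.31, so the groups overlapped. In this list 1 of 18 members was called over all genes and adjusted over the list alone. Edem1, of the degradation of misfolded glycoproteins, was 1.59-fold lower at 122 ± 20.6 against 194 ± 6.43 CPM. Pdia6, Xbp1 and Sdf2l1 were at 254 ± 63.7, 97.9 ± 15.9 and 60.4 ± 18.1 CPM, against 398 ± 51.2, 131 ± 16.4 and 86.5 ± 12.3. This call ended without ICI replicate 2 (adjusted p = 0.815), RT_ICI replicate 1 (0.196) or RT_ICI replicate 2 (0.108), and Edem1 was at 0.103 after the length and GC correction.

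Interferon response genes were lower in RT_ICI as lists, and ICI replicate 1 stood apart in the type I list. That list lay 1.69 above each gene's mean log2 CPM in ICI replicate 1, against 0.31 and -0.11 in ICI replicates 2 and 3 and -0.14, -1.25 and -0.51 in RT_ICI. Markers of cytotoxic T cells (2.69) and natural killer cells (2.01) were also highest in ICI replicate 1. The interferon-gamma list overlapped between the groups, at 1.04, 1.41 and -0.69 in ICI and 0.60, -0.77 and -1.59 in RT_ICI. All 23 tested genes of the type I interferon response had a negative log2 fold change, with a median of -1.27, and 0 were called over all genes or adjusted over the list alone (camera adjusted p = 4.77e-06, and adjusted p = 0.930 with an estimated correlation). In edgeR 13 were lower at an unadjusted p under 0.05, and DESeq2 called 11 and limma-voom 0. Ifi44 was at 1.70 ± 0.557 against 9.67 ± 8.70 CPM (adjusted p = 0.0521), Rigi, the RNA sensor, at 28.6 ± 7.90 against 63.6 ± 34.8, and Ifit2 at 21.6 ± 1.73 against 54.4 ± 37.8. ICI replicate 1 held 19.7 CPM of Ifi44 against at most 5.10 in ICI replicates 2 and 3, and without it the log2 fold changes of Ifi44 (-2.51) and Ifit2 (-1.33) were -1.47 and -0.61. Oas1a was at 35.9 ± 13.3 against 77.5 ± 33.6 CPM, but 98.7% of its transcript is near-identical to Oas1g. Of 20 interferon-gamma response genes 0 were called, over all genes or adjusted over the list alone (camera adjusted p = 0.00535, and adjusted p = 0.930 with an estimated correlation). Of these, 2 were lower at an unadjusted p under 0.05 in edgeR, and DESeq2 called 2 and limma-voom 0. Cxcl9, a chemokine that draws T cells, was at 9.54 ± 6.90 against 30.3 ± 12.2 CPM (adjusted p = 0.117) and Cxcl10 at 125 ± 42.9 against 213 ± 51.2. Gbp6 and Irgm2 were at 13.1 ± 8.41 and 33.0 ± 28.6 CPM against 47.2 ± 34.2 and 103 ± 60.8. Leaving out RT_ICI replicate 1 moved the log2 fold changes of Cxcl9 from -1.66 to -2.39 (adjusted p = 0.0323), of Gbp6 from -1.84 to -2.43 and of Irgm2 from -1.64 to -2.59. The interferon-gamma list was not called without ICI replicate 2 (adjusted p = 0.0722).

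Cytotoxic T cell genes differed between libraries of the same group. Their mean log2 CPM lay 2.69, 1.32 and 1.07 above each gene's mean in ICI replicate 1, ICI replicate 2 and RT_ICI replicate 1, and below it in the other 3 libraries. The list was called lower in RT_ICI (camera adjusted p = 0.00535, and adjusted p = 0.930 with an estimated correlation), with 0 of 19 members called over all genes or adjusted over the list alone, and the call ended without ICI replicate 1 (adjusted p = 0.0810). No member had an unadjusted p under 0.05 in edgeR, so that count was 0, as were those of DESeq2 and limma-voom. Cd8a, the co-receptor of killer T cells, was at 0.911 ± 1.02 against 5.58 ± 5.57 CPM (adjusted p = 0.203) and Gzmb, their main granzyme, at 6.03 ± 9.90 against 17.0 ± 14.6 (adjusted p = 0.641). Eomes, Gzmk and Cd27 were at 0.323 ± 0.124, 0.295 ± 0.396 and 0.371 ± 0.327 CPM against 0.866 ± 0.649, 2.87 ± 3.39 and 1.51 ± 1.48. With ICI replicate 1 left out the log2 fold changes of Cd8a (-2.61), Gzmb (-1.49), Eomes (-1.36), Gzmk (-3.31) and Cd27 (-2.03) were -1.51, -0.88, -0.62, -1.73 and -0.95. With RT_ICI replicate 1 left out those of Cd8a, Gzmb, Gzmk and Cd27 were -4.07, -5.97, -5.74 and -3.07, and with RT_ICI replicate 2 left out those of Gzmb and Gzmk were -0.89 and -2.63. Ifng and Foxp3 were below the filter on low counts, at 0.445 ± 0.691 and 0.140 ± 0.126 CPM in RT_ICI and 1.38 ± 2.19 and 0.173 ± 0.1001 in ICI. The checkpoint genes Pdcd1 (0.757 ± 0.921 against 0.636 ± 0.459 CPM) and Cd274 (31.2 ± 3.92 against 44.8 ± 20.5 CPM) were not called, nor was the antigen-presenting gene H2-K1 (152 ± 154 against 172 ± 78.9 CPM). RT_ICI replicate 1 held 330 CPM of H2-K1 against 63.6 and 62.0 in the other RT_ICI libraries, and without it the log2 fold change was -1.45 (adjusted p = 0.0535) against -0.18. That of Pdcd1 was -1.57 without RT_ICI replicate 1 and 0.92 without ICI replicate 1, against 0.25.

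**Figure D4:**
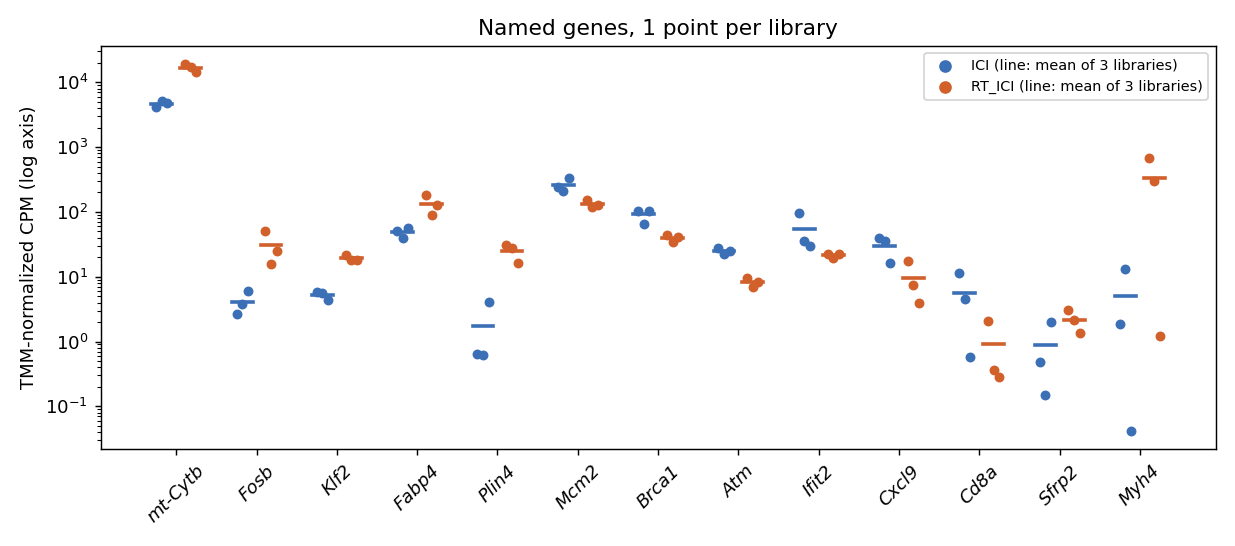
TMM-normalized CPM of 13 named genes on a log axis, 1 point per library, with the mean of each group as a line. Klf2 and Atm keep all RT_ICI libraries on one side of all ICI libraries, while Myh4 in RT_ICI spans 1.21 to 692 CPM.

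With all 6 libraries and no replicate block, no stromal list was called. Sfrp2, the secreted Wnt modulator in the title (chromosome 3, 83766321 to 83774316), was at 2.17 ± 0.850 CPM in RT_ICI and 0.889 ± 1.00 in ICI (SD, n = 3 each). Its log2 fold change was 1.27 with an SE of 0.81, and it was not called (adjusted p = 0.311, edgeR). ICI replicate 3 held 2.03 CPM of Sfrp2 against 0.489 and 0.151 in ICI replicates 1 and 2, and without it the log2 fold change was 2.76 (adjusted p = 0.106). Of 7 tested secreted Wnt modulators and 26 fibroblast genes 0 were called, over all genes or adjusted over each list alone (camera adjusted p = 0.485 and 0.410). At an unadjusted p under 0.05 in edgeR 0 Wnt modulators, and 3 fibroblast genes higher and 3 lower, were found; DESeq2 called 0 of the former and 2 fibroblast genes each way, and limma-voom 0. The fibroblasts list was called higher without ICI replicate 3 (adjusted p = 0.000462). Col1a1, the main fibrillar collagen, was at 176 ± 63.8 against 139 ± 122 CPM, and Fap, a marker of activated fibroblasts, at 1.05 ± 0.528 against 1.41 ± 0.898. ICI replicate 3 held 274 CPM of Col1a1 against 104 and 38.4 in ICI replicates 1 and 2, and without it the log2 fold change was 1.29 against 0.34. Of 18 pericyte and smooth muscle genes and 20 endothelial genes 0 were called, over all genes or adjusted over each list alone (camera adjusted p = 0.600 and 0.738). The pericytes and smooth muscle list was called lower without ICI replicate 2 (0.0402), and the endothelial cells list lower without RT_ICI replicate 1 (0.0320). At an unadjusted p under 0.05 in edgeR 1 pericyte gene was higher and 2 lower, DESeq2 called 3 lower and limma-voom 0, and endothelial counts were 0 by each. Pdgfrb was at 20.03 ± 1.36 against 18.8 ± 5.23 CPM, Rgs5 at 19.97 ± 5.40 against 45.02 ± 30.3 (adjusted p = 0.160), and the endothelial junction gene Pecam1 at 29.8 ± 27.7 against 36.9 ± 15.8. The log2 fold change of Rgs5 was -0.48 without ICI replicate 3 against -1.17, and that of Pecam1 -1.38 without RT_ICI replicate 1 against -0.30. Pmel, a melanosome gene of the tumour cells, was at 3853 ± 1066 against 4217 ± 198 CPM (adjusted p = 0.695).

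Among the other lists, none was called by camera. Of 18 melanocyte lineage genes Mlana rose 0.75 and Slc24a5 fell by 0.91 on the log2 scale (camera adjusted p = 0.528). Of 13 dedifferentiated melanoma genes Nes fell by 0.56 (0.838), and of 18 TGF-beta response genes Tgfbr1 fell by 0.60 (0.102). Of 10 leukocyte adhesion genes Cxcl13 and Ackr1 rose (0.0903), Ackr1 from 0.0447 to 0.867 CPM. Of 22 macrophage genes Cd163 rose by 1.98 while Cx3cr1 and Ms4a7 fell (0.528). Of 12 MHC class II genes Ifi30 rose (0.967), and of 21 hypoxia and glycolysis rows Adm and Pfkfb4 rose (0.555). Adjusted over the list alone, 2 TGF-beta genes were lower and 2 macrophage genes higher, and the other counts of these 7 lists were as over all genes. The lists of immune checkpoints (adjusted p = 0.528), CD4 helper and regulatory T cells (0.528), B and plasma cells (0.738), monocytes and neutrophils (0.846), dendritic cells (0.305), MHC class I presentation (0.391) and inflammatory cytokines (0.738) had 0 members called, over all genes or adjusted over each list alone. These 7 lists held, at an unadjusted p under 0.05 in edgeR, 0 to 4 genes higher and 0 to 2 lower, DESeq2 called 0 to 2 each way and limma-voom 0. Natural killer genes, with 4 tested members, had 0 in each of these counts. Leaving out RT_ICI replicate 1 made the lists of TGF-beta response (adjusted p = 0.0175), immune checkpoints (0.0210), dendritic cells (0.0248), MHC class I presentation (0.000692) and MHC class II presentation (0.0432) lower. The TGF-beta response list was also called lower without ICI replicate 2 (0.00391) and MHC class I presentation without ICI replicate 3 (0.00611). The list of leukocyte adhesion and lymphoid chemokines was called higher without ICI replicate 1 (0.0225), RT_ICI replicate 2 (0.00833) or RT_ICI replicate 4 (0.0227). For endothelial cells, B and plasma cells, monocytes and neutrophils, MHC class II and inflammatory cytokines the median or mean of the members and the direction of the test differed in sign.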

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

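The corrections for transcript length and GC content, and leaving out mitochondrial genes with their copies, ribosomal RNA rows and unnamed rows, were chosen after seeing the data. Counts of called genes (754 higher, 799 lower) stayed within 1.5 times under median-of-ratios scaling, the stricter filter, limma-voom, robust estimation off and both ways of leaving out mitochondrial genes. Upper-quartile scaling gave 497 lower, and no filter 1507 lower. DESeq2 gave 1746 higher and 1703 lower, and on the simulated data called 55 unchanged genes against 12 by edgeR and 7 by limma-voom. An adjusted p under 0.1 gave 1802 and 1833, and a log2 fold change of at least 1 in addition 431 and 156. The length and GC correction gave 261 and 229, and without RT_ICI replicate 1 it gave 1272 and 1355. Leaving out single libraries gave 0 (ICI replicate 1 or RT_ICI replicate 2) to 1564 higher and 0 (those, or ICI replicate 3) to 1545 lower (both highest without RT_ICI replicate 1). At an unadjusted p under 0.05 in edgeR these fits held 3701 to 6474 genes. The cause was not tested, except that looser or stricter thresholds change counts by construction. The depth limits genes near the floor of 3 counts, which is 0.0627 to 0.140 CPM per library.

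Called lists (7 higher, 6 lower) ranged from 3 to 8 higher and from 6 to 12 lower when single libraries were left out, with 3 and 12 without RT_ICI replicate 1. The length and GC correction without that library gave 12 lower. With an estimated correlation 0 were higher and 0 lower (2 and 0 at an unadjusted p under 0.05, camera), and with fry 1 and 0 (5 and 1 unadjusted). Over all alternatives, called lists kept direction and call in 197 cases, lost the call in 47 and reversed in 1, and lists not called stayed so in 293, passed in 28 and reversed in 37. Called named genes kept their call in 457 cases and lost it in 231. Named genes not called stayed so in 743, passed in 56 and reversed in 22. With the 500 most variable genes the mean correlation between groups was 0.486 against 0.950, and the first component (51.1%) no longer separated the groups.

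The reversed lists are given with adjusted p. Upper-quartile scaling turned monocytes and neutrophils (0.916) and MHC class II presentation (0.843). MHC class II presentation also turned with no filter (0.958), limma-voom (0.838), robust estimation off (0.989) and the length and GC correction (0.803). The stricter filter turned dedifferentiated melanoma (0.954) and monocytes and neutrophils (0.393). The correction without RT_ICI replicate 1 turned dedifferentiated melanoma (0.661), macrophages (0.110), monocytes and neutrophils (0.433), MHC class II presentation (0.0135), hypoxia and glycolysis (0.438) and oxidative phosphorylation (0.799). Reversed genes, as log2 fold changes, were Mki67 with upper-quartile scaling (0.012) and with the correction (0.17), Pdcd1 with limma-voom (-0.43), and, with the correction without RT_ICI replicate 1, Col1a1 (-0.046), Pdcd1 (-1.75) and Mki67 (0.34). The cause was not tested.

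Leaving out single libraries turned other lists and genes, none of them called with all 6 libraries and no replicate block. Over those fits adjusted p ran from 0.359 to 0.812 for dedifferentiated melanoma, 0.000462 to 0.913 for fibroblasts, 0.0402 to 0.924 for pericytes and smooth muscle, and 0.0320 to 0.987 for endothelial cells. It ran from 0.339 to 0.899 for B and plasma cells, 0.123 to 0.950 for macrophages, 0.358 to 0.808 for monocytes and neutrophils, 0.0432 to 0.815 for MHC class II presentation, 0.121 to 0.987 for inflammatory cytokines and 0.108 to 0.822 for hypoxia and glycolysis. Log2 fold changes ran from -0.12 to 1.29 for Col1a1, -0.87 to 0.11 for Fap, -0.14 to 0.22 for Pdgfrb, -1.38 to 0.11 for Pecam1, -1.57 to 0.92 for Pdcd1, -1.45 to 0.24 for H2-K1, -0.34 to 0.24 for Mki67 and -0.36 to 0.049 for Pmel. The cause was not tested.

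ICI and RT_ICI share only replicate numbers 1 and 2, and the labels do not say that a number marks a shared animal or day. Deviations from the group means correlated at 0.353 for number 1 and 0.0909 for number 2, against -0.320 to 0.270 for other pairs. With 2 shared numbers these values do not settle whether the numbers pair the samples, and no pairing was assumed. ICI replicate 3 and RT_ICI replicate 4 share their number with no other library, so a block on the number fits each of them exactly. The group difference and the spread it is judged against then come from numbers 1 and 2 alone. With the replicate number as a block, 400 genes were higher and 245 lower. Of these, 209 and 112 had been called in the same direction without it. With the block 9 lists were higher and 6 lower, of which 6 and 5 had been called before. The lists of cell cycle (adjusted p = 0.104) and p53 target genes (0.0874) lost their call. The lists of fibroblasts (1.16e-13), leukocyte adhesion and lymphoid chemokines (0.00646) and endothelial cells (0.0408) were called higher and MHC class I presentation (0.0233) lower. These list calls used camera at the preset correlation of 0.01. In the fit without the block the estimated correlation of the fibroblasts list was 0.761. Sfrp2 had a log2 fold change of 3.13 (adjusted p = 0.0181, edgeR) and Col1a1 of 1.62 (0.0112). Of the named genes 17 lost their call and 16 gained one. The block turned the lists of pericytes and smooth muscle (adjusted p = 0.386), endothelial cells, monocytes and neutrophils (0.785) and inflammatory cytokines (0.315). It also turned the genes Fap (0.13), Pecam1 (0.18), Pdcd1 (-0.59) and Mki67 (0.23, log2). Beyond the loss of ICI replicate 3 and RT_ICI replicate 4 from the comparison, the cause was not tested.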

Other observations

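The tests of a length and GC trend, of RT_ICI replicate 1, of scaling, of skeletal muscle and of fat tissue were chosen only after the result was seen. The genes named in the next paragraph were chosen after their values were seen.

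Several genes known to respond to glucocorticoids, and clock genes among them, rose in RT_ICI by edgeR. Per2 rose by 2.91 on the log2 scale (SE 0.37, adjusted p = 0.0218) from 0.844 ± 0.301 to 6.40 ± 1.66 CPM (SD, n = 3), and Per1 by 1.57 (adjusted p = 0.0189) from 33.0 ± 7.60 to 98.1 ± 7.30 CPM. Zbtb16 rose by 2.55, Tsc22d3 by 1.03, and Fmo2, a flavin monooxygenase, by 3.62 on the log2 scale. Fkbp5, another glucocorticoid target, was at 85.6 ± 19.6 against 76.4 ± 3.90 CPM (adjusted p = 0.525), and Klf9 (adjusted p = 0.395) and Sgk1 (0.0684) were not called either.

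Glucocorticoid-responsive transcription may account for part of these rises, as a hypothesis. A list of 16 other target genes, fixed before their values were looked at, had a median log2 fold change of 0.80 (camera adjusted p = 0.000328 over the 2 lists tested here, adjusted p = 0.366 with an estimated correlation, and adjusted p = 0.0944 with fry). Of these, 13 were positive and 3 called (Cdkn1c, Arrdc2 and Mt1), without RT_ICI replicate 1 camera gave adjusted p = 0.0154, and a list of 14 PPAR targets had a median of 0.33 (camera adjusted p = 0.0905), which leaves a fatty acid oxidation programme open. With fat markers as a covariate 83.4% of the median rise of 12 genes of this pattern was left, but those genes were picked as called and the markers overlap between the groups, so that outcome was fixed. Fat tissue stays open, as do stress, handling or time of day at harvest and the radiation itself, which were not tested.

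The rise of the 13 mitochondrially encoded genes, with a median of 1.76 on the log2 scale, was set against technical causes. A scaling factor moves all genes of a library alike. It leaves the gap of 1.75 between this median and that of all other tested genes as it is. TMM centres the other genes, so the gap restates the rise and is no separate test of scaling. With the share of muscle RNA as a covariate the median was 1.53. As with the fat markers that outcome was fixed, since all 13 genes were called and the muscle share overlaps between the groups. RT_ICI replicate 4 held less muscle RNA than ICI replicates 1 and 2 (0.00304% against 0.0330% and 0.0267%). It held more mitochondrial RNA (11.4% against 4.33% and 4.91%). ICI replicate 3 held 0.000703% muscle RNA and 4.34% mitochondrial RNA. These shares argue against muscle as the cause of the rise in RT_ICI replicate 4, and so as the whole cause. RT_ICI replicates 1 and 2 held the most muscle RNA (0.277% and 0.152%) and the most mitochondrial RNA (14.6% and 12.5%). A part played by muscle stays open there. After the length and GC correction the median was 1.62, which argues against that trend as the whole cause. Differences in RNA quality, tissue handling or cell death between the groups were not tested and cannot be excluded with these files.

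Neither the length and GC trend nor RT_ICI replicate 1 accounted for all called genes. After the correction 29.2% of 1548 calls stayed past the threshold, and the median absolute log2 fold change of the calls that ended went from 0.78 to 0.58, with SE 0.17 and 0.16. Without RT_ICI replicate 1, 95.8% stayed. A trend of this kind can come from RNA integrity or library preparation, which was not tested, so it stays open for the calls that ended.

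The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 754 genes higher and 799 lower, and 1 of 10 splits, the real one, gave as many higher or lower. The highest other count was 0, with 154 to 1813 genes at an unadjusted p under 0.05 in edgeR. For gene lists, called with camera at a preset correlation, the real split gave 7 higher and 6 lower, the highest other count was 19, and 10 of 10 splits gave at least 7, and so at least 6, in one direction or the other. This points to a structure of the samples in which genes of a list vary together, whichever way the libraries are grouped.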
